A study of Mus musculus with 3 samples.

How the data were processed

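Single-cell RNA sequencing libraries (10x, 3' tags) of mouse bladder urothelium were used, 1 from wild-type, 1 from Lpar6 knockout and 1 from Cab39l knockout mice. Per the labels, each library was made from the pooled cells of 15 mice, so animals cannot be told apart and there is 1 library per group. The deposited values are raw UMI counts per gene and cell barcode, in matrices from which the authors had already removed empty droplets. The submitters' processing notes name Cell Ranger 3.0.2 and the mm10 genome build, and the annotation release behind the 31053 genes is not given in the sources used here. The matrices held 8085, 8293 and 9406 barcodes (25784 in all). Whole-number values with unequal totals per barcode were checked, and the gene order was the same in the 3 libraries. Gene positions and transcript lengths were taken from the GENCODE vM21 annotation, in which 30934 of the gene identifiers (99.6%) were found. No reads were used, and no aligner was run.

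Cells with fewer than 500 genes (1537, 1074 and 1095 barcodes in wild type, Lpar6 knockout and Cab39l knockout) or with more than 20% mitochondrial UMIs (2222, 1381 and 1654) were left out, which passed 4326, 5838 and 6657 cells. Doublet scores were computed per library with the Scrublet method in scanpy 1.11.5. Its own threshold marked 34 of 16821 cells (0.2%), under the minimum of 0.5%, so the top-scoring cells up to a rate of 6% were removed instead (259, 350 and 399). Kept were 4067, 5488 and 6258 cells, with median depths of 16717, 24555.5 and 22919 UMIs. Counts were scaled to 10000 UMIs per cell and log-transformed. From 2000 genes that varied within libraries, without sex-linked, ribosomal, mitochondrial and haemoglobin genes, Lpar6 and Cab39l, 30 components were computed. A graph of 15 neighbours was grouped by the Leiden method (leidenalg 0.10.2) at a resolution of 1, on the 3 libraries together and with no batch correction. This gave 23 clusters. A cluster was called urothelial-like when the summed CPM of urothelial markers reached 50% of that over all cells, and such clusters with a median depth under a fraction of 0.333 of their library's median were set aside as low depth. Names such as basal-like came from 17 marker lists, and needed a marker among the 10 leading genes and at least 3 markers higher than in the other cells, so marker genes of a class are not results within it. Clusters that met no list stayed unnamed. Immune-like levels and folds were taken over B-like, T- or NK-like and macrophage- or dendritic-like cells. Immune-like shares also count neutrophil-like cells.

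UMIs were summed over the cells of each library and class and scaled to a common total (CPM), and folds are log2 of (CPM + 1) ratios. No test was run because cells are not replicates. Levels have exact 95% Poisson intervals and shares exact 95% binomial intervals. A fold against 0 counts was computed at a floor of 3 counts over the group. Depth sets the precision, with 71158927, 115869831 and 143271834 urothelial-like UMIs but only 62 intermediate-like and 44 umbrella-like wild-type cells. Named genes were the targeted genes, the 8 highest and 8 lowest genes at least 2-fold apart in the same direction in every compared class, the 5 highest and 5 lowest in each class, and 2 to 4 members of each list. Eligible genes had at least 50 UMIs over both libraries and 20 CPM in the higher one, and ribosomal, mitochondrial, haemoglobin, sex-linked and predicted genes were not ranked. For 32 gene lists, the median log2 of members with at least 20 UMIs was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. List members at least 1.5-fold apart were counted. The folds of both knockouts were correlated over genes with at least 50 UMIs and set beside 100 simulated unchanged libraries. For shares of cells with a UMI, each cell was thinned at random to 1900 UMIs, the 10th percentile of the kept cells rounded down. These filters, lists, naming rules and comparisons were fixed before the data were examined, as were most of the alternatives. The alternatives covered the gene and mitochondrial filters, doublets, resolution, library differences in clustering, thinning, scaling, pseudocount, low-count filters and the weight of cells. Chosen after seeing the data were the trend with transcript length, all urothelial-like cells and cluster 1 alone as the cells summed, clustering without 585 genes, the Krt15 level and share, and the count of cells holding mitosis genes. TMM and median-of-ratios factors were computed in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. They shift basal-like log2 values against wild type by 0.32 (Lpar6) and 0.35 (Cab39l), or by 0.30 and 0.34. Figures were drawn with matplotlib 3.10.9.

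The steps were tested on simulated data. Known folds of 1.5, 2 and 4 were recovered in 100, 98.5 and 93.9% of changed genes for the Lpar6 knockout (5551 genes) and 100, 100 and 98.5% for the Cab39l knockout (5469 genes), and 0.0% of unchanged genes came out 2-fold apart. Of 200 unchanged lists 7.0% lay outside the middle 95% of random lists in each comparison, and 100% of 50 lists raised 1.3-fold were found above it. A trend with length put in at rank correlations of -0.97 and -0.99 was taken down to -0.02 in both. Cells drawn from 1 profile gave thinned Krt5 shares of 43.2, 45.5 and 43.9%. Simulated B and macrophage cells came back to clusters of their own in 99.7 to 100% of cells over 4 configurations of profiles and cell numbers, but urothelial classes in 0.0 to 100% of cells. Earlier draws of this simulation were also run and are not reported. Because of this uneven recovery no direction is drawn from urothelial class shares.

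Left out were cells below the filters and, from the comparisons, clusters of low depth and cells of unnamed clusters outside the urothelium. No genome sequence, bulk data or human data were used here. Some genes that met the naming rule are not reported here.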

Results

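The lining of the bladder (urothelium), an epithelium of basal, intermediate and superficial umbrella cells, was profiled by droplet-based 3' single-cell RNA sequencing in 3 mouse libraries. One library came from wild-type mice, one from Lpar6 knockout mice and one from Cab39l knockout mice, each made from the combined cells of 15 animals. The deposited matrices held 8085 wild-type, 8293 Lpar6 knockout and 9406 Cab39l knockout barcodes, with 101977647, 139250807 and 175075246 unique molecular identifiers (UMIs). After filtering, 4067, 5488 and 6258 cells were kept. Of these, 2998, 4457 and 5032 lay in urothelial-like clusters, with median depths of 21405, 26605 and 28865 UMIs per cell. Levels are CPM, the UMI counts of the summed cells of a class scaled to a common total. With 1 library per group, no difference had a replicate check, no test was made and no p-value is given. Levels carry exact 95% Poisson intervals and shares exact 95% binomial intervals, and both cover counting error only.

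The targeted genes were examined first. Lpar6 encodes a receptor for lysophosphatidic acid, and Cab39l encodes a scaffold protein of the LKB1 kinase complex. No Lpar6 UMI was present in the Lpar6 knockout library, neither in its 4457 urothelial-like cells nor in any of its 8293 barcodes, whereas the level was 13.9 CPM (13.0 to 14.8, from 988 UMIs) in wild type and 12.3 CPM (11.7 to 12.9, from 1757 UMIs) in the Cab39l knockout. Computed at a floor of 3 counts over the group, Lpar6 was 538-fold lower in its knockout than in wild type. The exact upper limit for 0 counts is 3.7 UMIs (0.032 CPM), so this fold is not a 95% lower bound. For cells, 0 of 4457 allows a share of up to 0.083% with a UMI. Cab39l was lower in its own knockout but still present, at 31.8 CPM (30.9 to 32.8) against 112 CPM (109.8 to 115) in wild type and 93.6 CPM (91.8 to 95.4) in the Lpar6 knockout. The knockout level was 3.5-fold lower than wild type (3.4 to 3.66). Both genes lie on the plus strand of mm10 chromosome 14, Lpar6 (ENSMUSG00000033446) from 73237895 to 73243294 and Cab39l (ENSMUSG00000021981) from 59440972 to 59585764, 13.8 Mb apart. Lpar6 lies in intron 17 (73216780 to 73262528) of the 27-exon transcript Rb1-201, which runs on the opposite strand. The labels do not say which part of either gene was deleted, and a 3' tag outside the deleted part checks nothing.

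**Figure D1:**
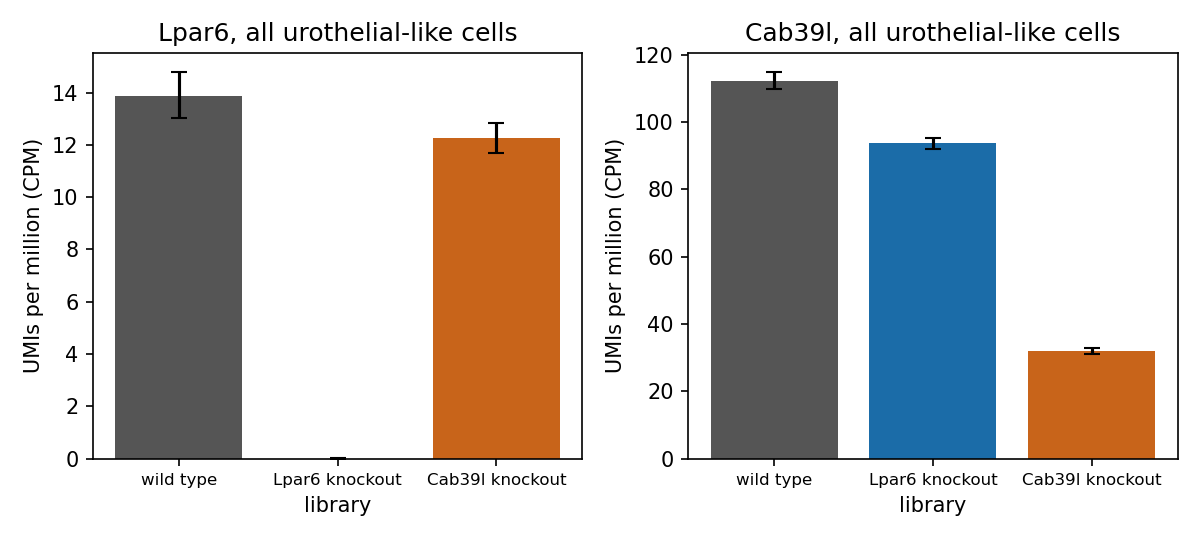
Lpar6 and Cab39l levels (CPM, from 0) in the summed urothelial-like cells of the wild-type, Lpar6 knockout and Cab39l knockout libraries, as bars with exact 95% Poisson intervals. Lpar6 stands at 0 in its knockout and Cab39l at 31.8 CPM in its own, against 112 CPM in wild type.

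The series title asks whether loss of either gene disturbs the passage of urothelial cells from basal to luminal. The basal keratins Krt15 and Krt5 were lower in the Lpar6 knockout library than in both others. Krt15, a keratin of basal cells, was 234 CPM (231 to 237) there, against 1119.5 CPM (1111.8 to 1127.3) in wild type and 1152.8 CPM (1147.2 to 1158.3) in the Cab39l knockout. Krt5, the main basal keratin of the urothelium, was 189 CPM (186 to 191), against 302 CPM (298 to 306) and 325 CPM (322 to 328). Krt4, a keratin listed among the intermediate markers, was 27.8 CPM against 66.7 and 80.5 CPM. Other basal genes were lower in both knockout libraries, among them the transcription factor Trp63 (95.5 and 98.0 CPM against 159 CPM) and, named after their values were seen, Itga6 (29.96 and 30.6 against 53.6 CPM), Itgb4 (11.7 and 14.6 against 29.2 CPM), Cd44 (15.6 and 19.6 against 38.3 CPM) and Lamb3 (22.8 and 25.1 against 46.6 CPM). Long transcripts in general were lower in both as well, with median log2 values of -0.71 (Lpar6) and -0.79 (Cab39l) from 4.94 or 4.93 kb. The levels of these basal genes are given without that trend taken off, so no loss specific to basal genes is drawn from them. Psca, an intermediate marker, was 955 CPM (948 to 963) in wild type, 1536.9 CPM (1529.7 to 1544) in the Lpar6 knockout and 1312.8 CPM (1306.9 to 1318.8) in the Cab39l knockout. Among the uroplakins, which form the plaques of the umbrella cell surface, Upk3a was 4764, 6203 and 5516 CPM and Upk1a 1823.6, 2766 and 2875 CPM, while Upk2 was 853, 539 and 572 CPM. Krt20 of umbrella cells was 53.9, 42.5 and 32.9 CPM. The median gene over all urothelial-like cells lay at a log2 of -0.34 in the Lpar6 knockout and -0.31 in the Cab39l knockout against wild type, and the log2 of Krt20 in the Lpar6 knockout, -0.33, is level with that median. The Krt15 level over all urothelial-like cells was singled out after its values were seen.

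The shares of cells with a UMI were compared after every cell was thinned to 1900 UMIs, which left out 13, 19 and 16 urothelial-like cells. Krt5 was found in 43.1% of wild-type (41.3 to 44.9), 29.5% of Lpar6 knockout (28.1 to 30.8) and 45.1% of Cab39l knockout cells (43.7 to 46.4). In B-like and T- or NK-like cells, which should lack it, the shares were 13.1, 16.2 and 7.63%. There 107, 7 and 20 cells were left out, and those measured had median depths of 2876.5, 2498 and 3342 UMIs before thinning. Unthinned, the Krt5 shares were 93.1, 88.3 and 94.8%. Krt15 was found in 55.8, 19.1 and 61.0% of urothelial-like cells, against 27.8, 18.9 and 26.7% in the lymphoid cells, of which the Lpar6 knockout had only 37 (7.96 to 35.2%). In basal-like cells the shares were 81.9, 67.6 and 91.7%, in intermediate-like cells 83.6, 72.8 and 90.5% and in umbrella-like cells 20.5, 7.24 and 26.8%. Within each class the Lpar6 knockout lay closer, in points, to the other libraries than over all urothelial-like cells. Krt15 helps name the basal-like class, so its share there is no result. Unthinned Krt15 shares over all urothelial-like cells were 84.2, 46.2 and 90.2%. Upk3a was found in 98.8, 99.6 and 99.6% of urothelial-like cells and in 71.9, 91.9 and 80.2% of lymphoid cells, with unthinned shares of 99.9, 99.98 and 99.98%, and separated nothing. Both Krt5 and Upk3a were found in 42.4, 29.4 and 44.9%, and neither in 0.536, 0.248 and 0.159%. Cells with 2 or more cycling markers made up 0.369, 0.113 and 0.299% (unthinned 17.3, 16.5 and 17.7%), against 4.38, 0 and 2.29% in the lymphoid cells. These urothelial shares rest on 11, 5 and 15 cells. The Lpar6 knockout lay -0.26 points from wild type (-0.556 to -0.018), a difference that turned to 0.04 with at least 200 genes per cell and to 0.08 with called doublets kept, and the Cab39l knockout -0.07 points (-0.388 to 0.198).

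**Figure D2:**
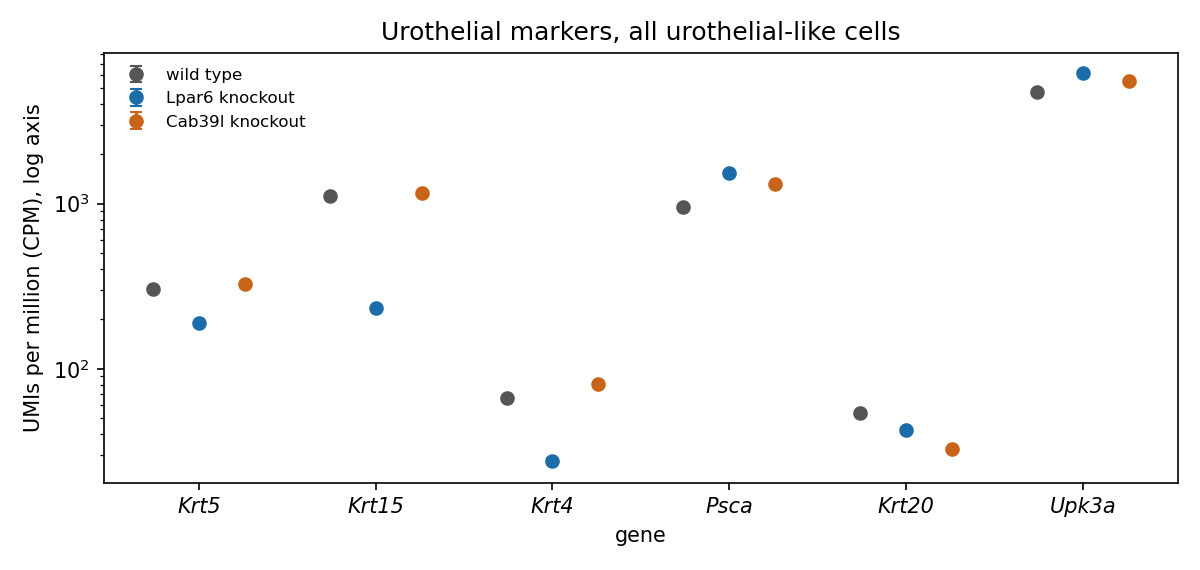
Levels of Krt5, Krt15, Krt4, Psca, Krt20 and Upk3a (CPM, log axis) in the summed urothelial-like cells of the 3 libraries, with exact 95% Poisson intervals that are smaller than the points. Krt15 is 234 CPM in the Lpar6 knockout, 1119.5 CPM in wild type and 1152.8 CPM in the Cab39l knockout.

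Long transcripts were lower in both knockout libraries than in wild type. Among them were Dst, which ties the cytoskeleton to hemidesmosomes (148 CPM in wild type, 56.8 in the Lpar6 knockout and 54.3 in the Cab39l knockout), the scaffold Ahnak (386, 186 and 186 CPM) and the non-muscle myosin Myh9 (196, 80.4 and 74.7 CPM). The rank correlation of the log2 with transcript length, across genes that are not independent replicates, was -0.70 over 5509 genes for the Lpar6 knockout and -0.73 over 5518 genes for the Cab39l knockout, but 0.20 between the knockouts. Transcripts of up to 2.0 kb had a median log2 of 0.15 in each knockout, and those from 4.94 or 4.93 kb -0.71 and -0.79. In immune-like cells the correlations with length were -0.22 over 5930 genes (Lpar6) and -0.25 over 6043 genes (Cab39l). Transcripts from 4.74 or 4.72 kb had medians of -0.34 and -0.39 there. Urothelial-like cells drawn down to the immune-like totals gave correlations of -0.51 and -0.64. The trend was thus weaker in immune-like cells. Uroplakins there stood at 14.4% of their urothelial level in wild type, 25.7% in the Lpar6 and 23.5% in the Cab39l knockout. Urothelial RNA may therefore be among the immune-like counts, and the mix of immune-like classes differed between the libraries. Whether the trend is confined to urothelial-like cells cannot be told from these values. Among urothelial-like cells, those of wild type were also the shallowest and had the highest median mitochondrial share, 9.13% against 6.28 and 6.18%. Because of this shift, log2 values below are relative to the median gene of their class where so named.

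**Figure D3:**
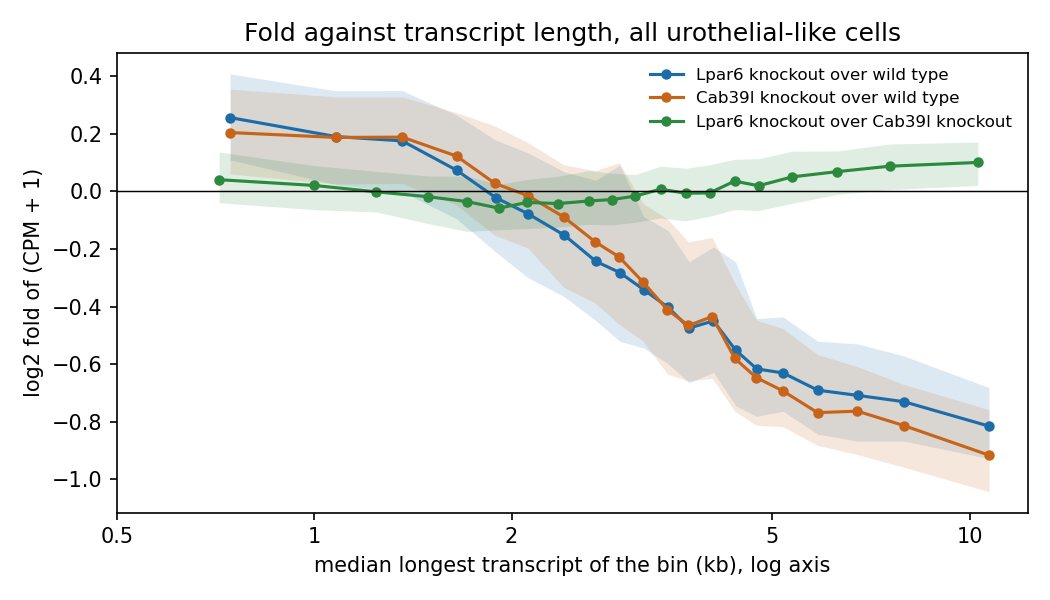
Median log2 (CPM + 1) ratio of genes in 20 bins of transcript length (kb, log axis) over all urothelial-like cells, for each knockout over wild type and for the Lpar6 over the Cab39l knockout, with bands from the 25th to the 75th percentile of genes. Both knockout-over-wild-type lines slope down with length, at rank correlations of -0.70 and -0.73 across genes.

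The Lpar6 knockout was compared with wild type to ask what loss of the receptor does to urothelial cells. Adam28, Lars2 and AY036118 were lower in each compared class, basal-like, intermediate-like and umbrella-like. Adam28 (ENSMUSG00000014725), a membrane metalloprotease, was 19.6 CPM (18.8 to 20.5) over all urothelial-like cells against 97.3 CPM (95.02 to 99.62), -1.91 relative to the median. Lars2, a mitochondrial leucyl-tRNA synthetase, was 47.7 against 246 CPM and AY036118 63.2 against 184 CPM. Both were also lower in the Cab39l knockout (42.2 and 82.9 CPM), and Lars2 in immune-like cells was 341 CPM in wild type against 107 and 74.9 CPM. Dmtn (ENSMUSG00000022099), the actin-bundling protein dematin, was higher, at 21.1 CPM (20.2 to 21.9) against 3.98 CPM (3.53 to 4.47), a relative log2 of 2.49. Ly6k, a membrane-anchored Ly6 protein, was 300.1 CPM (297 to 303) against 81.7 CPM (79.6 to 83.9), and Hddc3, a phosphatase, 42.8 CPM against 14.6 CPM. Rnase4, a secreted ribonuclease, was 177 CPM against 101 CPM. Sncg, gamma-synuclein, was named for its level in intermediate-like cells and had 1485 UMIs (12.8 CPM) against 17 (0.239 CPM). The Cab39l knockout resembled wild type in Adam28 (83.8 CPM), Dmtn (3.57 CPM), Hddc3 (15.6 CPM) and Sncg (0.321 CPM). Adam28 and Dmtn lie 4.63 and 2.64 Mb from Lpar6, and Rnase4 and Sncg on the same chromosome. Only 62 wild-type cells were intermediate-like and 44 umbrella-like, and Lars2 and AY036118 are among the leading genes of the cluster that holds 1066 of the 1385 wild-type basal-like cells.

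In basal-like cells, immediate early genes, which answer stress and growth signals, were lower in the Lpar6 knockout. Of 17 measured, 8 were at least 1.5-fold lower and none that much higher, with Egr1 at 15.4 against 73.8 CPM, Fos at 115 against 186 CPM and Zfp36 at 56.2 against 96.2 CPM. The list's median log2 was -0.47, against -0.20 for random lists of like expression (percentile 1.7). Junction genes were lower by a median of -0.58 (random -0.17, percentile 0.2), with Tjp1 at 62.1 against 121 CPM, Cgn at 38.4 against 68.3 CPM and the cadherin Cdh1 at 101 against 172 CPM. Luminal keratins and transcription factors had a median of -0.48 (random -0.07, percentile 0.5), with Grhl2 at 30.0 against 47.8 CPM and Ehf at 161 against 249 CPM. MHC class I presentation stood above random lists, at 0.20 against -0.23 (percentile 99.8), with the immunoproteasome subunit Psmb8 at 49.4 against 31.6 CPM and H2-D1 at 629.6 against 509 CPM. Mitochondrially encoded genes had a median of -0.33 (random 0.08, percentile 0.6), which turned to 0.09 when cluster 1 alone was compared. MHC class II genes had a median of -0.98 (random -0.26, percentile 0.0), but the members went both ways. Cd74, H2-Aa and H2-Ab1 were lower, with 3, 3 and 5 UMIs in the Lpar6 knockout against 115, 46 and 71, while H2-Eb1 (18.8 against 14.3 CPM) and H2-DMb1 (5.18 against 3.91 CPM) were higher. Over all urothelial-like cells Cd74 stood at 3.27 CPM in wild type, against 5898 CPM in its 670 immune-like cells other than neutrophil-like ones. With neutrophil-like cells, immune-like cells made up 17.7% of kept wild-type and 1.99% of kept Lpar6 knockout cells. These 6 lists kept their side outside the middle 95% of random lists once the trend with transcript length was taken off. The Notch pathway (-0.57, percentile 1.6) and nuclear oxidative phosphorylation (0.27, percentile 99.9) did not, and moved to percentiles 31.7 and 92.3, the last with a median turned to -0.12. In cluster 1 alone, with 319 wild-type and 356 Lpar6 knockout cells, MHC class I presentation (0.28, percentile 100) and junctions (-0.26, percentile 0.9) stayed outside, while immediate early genes (-0.09, percentile 47.5) and luminal keratins and transcription factors (-0.16, percentile 6.2) did not. Over the 32 lists, 6 of 399 measured members were at least 1.5-fold higher and 90 lower, a split that TMM scaling moved to 40 and 30. Most basal-like cells of wild type lay in cluster 4, led by Gm26917, Krt15, mt-Nd6, Gm42418, Lars2, Neat1 and Malat1, and most of the Lpar6 knockout (356 of 445) in cluster 1, led by Krt15, Cyp2f2, Trf, Aldh3a1 and Krt5.

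The Cab39l knockout was compared with wild type to ask what loss of the LKB1 partner does. In every compared class Cd59a (ENSMUSG00000032679), an inhibitor of complement, was lower, at 7.13 CPM (6.70 to 7.58) against 28.2 CPM (26.9 to 29.4). Also lower in every class were the golgin Golga4 (80.2 against 225 CPM), the dynein subunit Wdr60 (9.82 against 30.9 CPM), Secisbp2l (16.3 against 38.0 CPM), the DNA damage ubiquitin ligase Rnf168 (9.72 against 22.6 CPM), Hist1h2bc (38.2 against 85.2 CPM) and Lars2 (42.2 against 246 CPM). These 6 were lower in the Lpar6 knockout library as well, whereas Cd59a there, at 26.8 CPM, lay near wild type. The linker histone Hist1h1e was 3.14 against 30.2 CPM, and 8.1 CPM in the Lpar6 knockout. Spink1, a trypsin inhibitor of secretory glands, was 41.8 against 4.97 CPM. In immune-like cells of the Cab39l knockout Spink1 reached 1466 CPM (1762 UMIs) against 42.8 CPM in wild type, and it leads an unnamed cluster together with Sbp and Pbsn. The histone genes have near-identical copies, and their values are uncertain.

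In basal-like cells of the Cab39l knockout, immediate early genes were lower too, with 9 of 17 at least 1.5-fold lower and none that much higher, a median log2 of -0.66 (random -0.20, percentile 0.0) and Egr1 at 10.0 against 73.8 CPM. Heat shock genes had a median of -0.55 (random -0.13, percentile 1.7), with Hsph1 at 11.4 against 26.7 CPM. Glycolysis stood above random lists, at 0.13 against -0.14 (percentile 98.7), with Tpi1 at 177 against 120 CPM and Pgk1 at 65.9 against 49.9 CPM. Mitochondrially encoded genes had a median of -0.28 (random 0.08, percentile 1.6), which turned to 0.07 under TMM scaling, 0.06 under median-of-ratios scaling and 0.13 in cluster 1 alone. These 4 lists kept their side after the length trend was taken off. The LKB1 and AMPK pathway, to which Cab39l belongs, had a median of -0.55 (random -0.33, percentile 2.5), with Prkab2 at 9.80 against 20.9 CPM, Sik2 at 14.8 against 30.5 CPM and the paralog Cab39 at 65.2 against 119 CPM, but lay at percentile 72.7 without the length trend. Likewise YAP and TEAD targets (-0.65, percentile 0.5), nuclear oxidative phosphorylation (0.28, percentile 99.9) and xenobiotic enzymes (0.12, percentile 98.1) moved to percentiles 48.0, 95.6 and 42.1, with the median of oxidative phosphorylation turned to -0.09. In cluster 1 alone immediate early genes (-0.36, percentile 0.3) and heat shock genes (-0.26, percentile 1.9) stayed outside, and glycolysis lay at 0.07, on the upper limit of the middle 95%. Over the 32 lists, 2 of 404 measured members were at least 1.5-fold higher and 100 lower, and TMM scaling moved this to 36 and 28. Most basal-like cells of the Cab39l knockout (1202 of 1436) lay in cluster 1 and most of wild type in cluster 4.

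Set against each other, the knockouts differed in the genes that had stood apart from wild type in one of them. The choice of these genes largely builds that difference in, so it is no separate finding. In the Lpar6 over the Cab39l knockout, over all urothelial-like cells, the log2 was -2.30 for Krt15, -2.04 for Adam28, 2.27 for Dmtn, 1.77 for Cd59a and 1.35 for Ly6k. In this comparison the median gene lay at 0.01. MHC class I presentation was higher in the Lpar6 knockout, with a median log2 of 0.16 (percentile 100), Psmb8 at 73.2 against 58.0 CPM and B2m at 457 against 333 CPM. The interferon list was higher by 0.14 (percentile 100), with Ifitm3 at 85.4 against 71.8 CPM. Basal keratins and adhesion were lower by -0.14 (percentile 0.0) and the G2 and mitosis list by -0.21 (percentile 0.0), where 5 cells of the Cab39l knockout held 396 of its 503 UMIs of Ube2c, Cdk1, Birc5, Mki67 and Ccnb1. All 10 lists outside the middle 95% of random lists in this comparison kept their side without the length trend. Immune-like cells, which carry MHC transcripts, made up 1.99% of the kept Lpar6 knockout and 3.595% of the kept Cab39l knockout cells.

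The folds of both knockouts against the shared wild-type library were compared in each class. In basal-like cells, unchanged libraries simulated against a redrawn wild type gave a correlation of 0.345 and a covariance of 0.0017. The observed correlation across 5536 genes was 0.868, and the covariance was 0.1498. Of these genes, 44 were at least 2-fold lower in both, where independent lists would share 3.1, and 0 were that much higher in both. TMM scaling gave 7 lower and 7 higher, and without the length trend, at a pseudocount of 10 CPM and in cluster 1 alone 23, 10 and 8 were lower in both. The simulated libraries hold counting error only, and the 3.1 takes no account of the shared wild type. That single wild-type library cannot be split. Part or all of the excess may come from it, so no shared effect of the knockouts is drawn from these values. With the length trend taken off, the correlation was 0.769 and the covariance 0.0733. In cluster 1 alone the correlation was 0.677 against 0.633 in the simulated libraries, with a covariance of 0.0495 against 0.0073. In intermediate-like and umbrella-like cells the correlations, 0.704 and 0.795, lay below the 0.757 and 0.942 of the simulated libraries, but the covariances, 0.1748 and 0.069, lay above their 0.0478 and 0.0274.

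Named classes took different shares of the urothelial-like cells, but no direction is drawn from them. Basal-like cells made up 46.2% of wild type (44.4 to 48.0), 9.98% of the Lpar6 knockout (9.12 to 10.9) and 28.5% of the Cab39l knockout (27.3 to 29.8). Umbrella-like cells made up 1.47, 17.1 and 18.6%, intermediate-like cells 2.07, 2.38 and 4.81%, and cells in unnamed urothelial-like clusters 50.3, 70.5 and 48.0%. Krt15 and Krt5, which help define the basal-like clusters, differed between the libraries. At a Leiden resolution of 2 the basal-like share of the Lpar6 knockout was 0.55 points above wild type, where it was -36.2 points at the resolution used, and the basal-like difference of the Cab39l knockout (18.86 points) and the umbrella-like differences of both knockouts (-5.55 and -4.32 points) turned sign there as well.

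**Figure D4:**
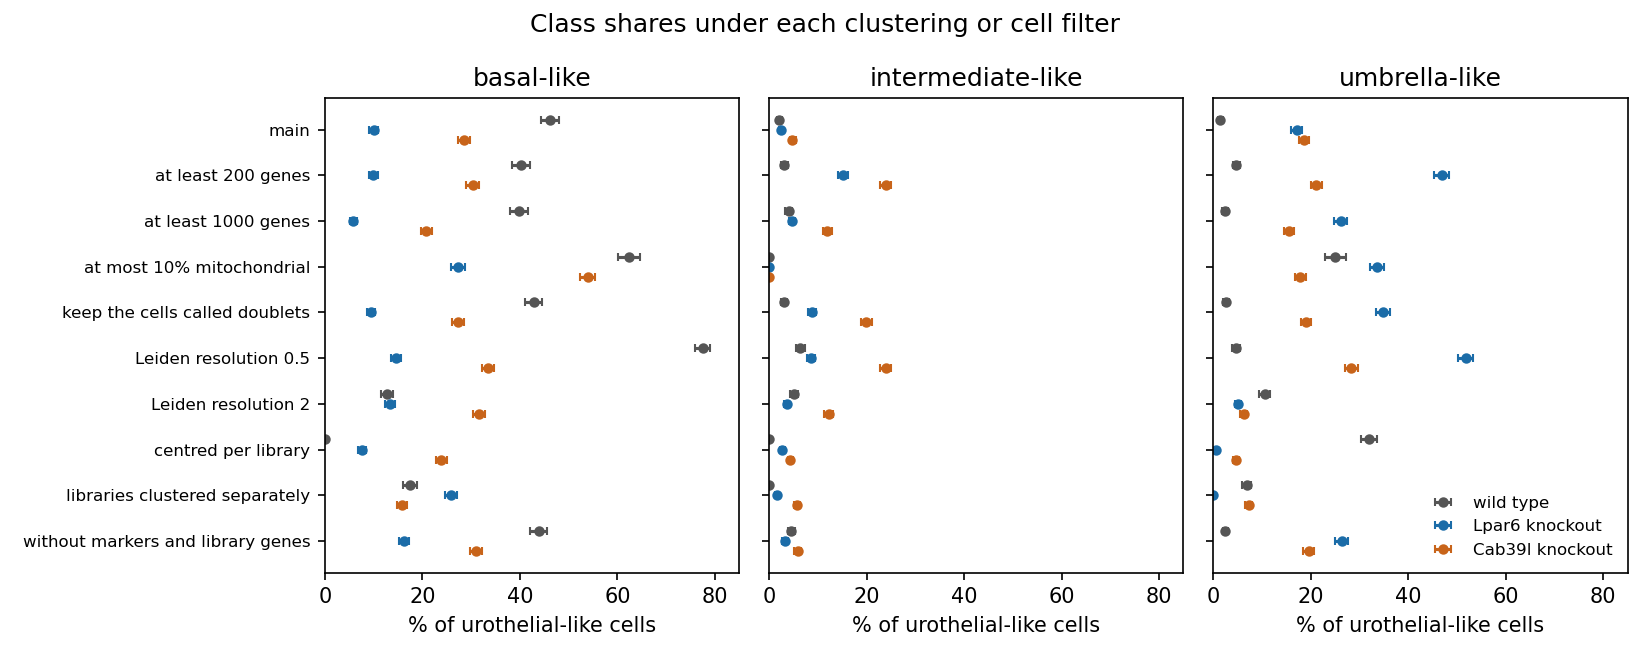
Basal-like, intermediate-like and umbrella-like shares of urothelial-like cells (percent) in the 3 libraries under each clustering and filter setting, with exact 95% binomial intervals. The basal-like share of wild type is 46.2% at the setting used, and the order of the libraries is not the same at every setting.

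Cells other than urothelial ones also differed between the libraries. Immune-like cells made up 17.7% (16.5 to 18.9) of kept wild-type cells, 1.99% (1.63 to 2.39) of the Lpar6 knockout and 3.595% (3.15 to 4.09) of the Cab39l knockout. T- or NK-like cells numbered 244, 15 and 34, and B-like cells made up 4.50, 0.528 and 1.87% and macrophage- or dendritic-like cells 5.98, 1.18 and 1.18%. Neutrophil-like cells were 1.20% of wild type, and 0 of 5488 and 0 of 6258 cells allow up to 0.067 and 0.059%. Fibroblast-like cells were 0.418, 1.09 and 0.240%. A cluster named seminal vesicle- or prostate-like held 16 cells, all of the Cab39l knockout, and an unnamed cluster led by Sbp, Spink1 and Pbsn held 38, 11 and 108 cells. The seminal vesicle or prostate markers summed to 35.7, 0.676 and 632 CPM over all kept cells. Over all urothelial-like cells, haemoglobin and other erythroid genes summed to 293, 136 and 38.6 CPM. Xist, transcribed from the inactive X of female cells, was 705, 571 and 352 CPM, and the Y-linked Ddx3y 22.8, 13.9 and 20.4 CPM, so every pool held cells of both sexes.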

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

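No explanation was tested for the results in this part, and the rule that picked them was set before the data were examined. They are shares of kept cells that lie above the wild-type library in clusters that no comparison uses, either because the cells are of low depth or because they met no marker list. All differences are between single libraries.

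Among clusters of low depth, cluster 5 held 9.02% of kept Lpar6 knockout cells (8.28 to 9.81) and 9.06% of Cab39l knockout cells (8.36 to 9.80), against 4.23% of wild type (3.63 to 4.89). It is led by the haemoglobin genes Hbb-bs, Hba-a1, Hba-a2 and Hbb-bt and by Alas2, all 5 of the erythroid markers, with median depths of 1389, 2029 and 1064 UMIs. In urothelial-like cells the order is the other way round, since erythroid transcripts there are highest in wild type (293 CPM against 136 and 38.6 CPM). Cluster 10, led by the non-coding transcripts Meg3, Tsix, Neat1 and Malat1, held 3.72% of Lpar6 knockout cells (3.23 to 4.25) against 1.72% of wild type (1.34 to 2.17). Cluster 15, led by Fabp4, Nupr1, Ttr and Clu, held 2.55% of Lpar6 knockout cells (2.15 to 3.003), which is 140 cells, against 0.074% (3 cells) of wild type and 0.24% (15 cells) of the Cab39l knockout. Fabp4 and Clu also lead the umbrella-like cluster.

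Outside the urothelium, both clusters that stood above wild type did so in the Cab39l knockout. Only cluster 16 has a leading gene (Pbsn) on the seminal vesicle or prostate list. Cluster 12, led by Akr1b7, Spink8, Crisp1 and Defb42, held 2.76% of Cab39l knockout cells (2.37 to 3.20) against 1.23% of wild type (0.914 to 1.62) and 0.219% of the Lpar6 knockout. Cluster 16, led by Sbp, Spink1, Pbsn and Tgm4, held 1.73% (1.42 to 2.08) against 0.934% (0.662 to 1.28) and 0.2%. In the immune-like cells of the Cab39l knockout, Sbp stood at 825 CPM and Akr1b7 at 94.8 CPM, against 28.1 and 40.4 CPM in wild type and 0 in the Lpar6 knockout. Sbp was 3.57, 0.58 and 13.8 CPM in urothelial-like cells of wild type, the Lpar6 knockout and the Cab39l knockout.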

How the results depend on the processing

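The alternatives on transcript length, on all urothelial-like cells, on cluster 1 alone, on clustering without fixed markers and genes 2-fold apart, and those for the Krt15 level and share were chosen only after the result was seen. The cause was not tested for the values below that moved or reversed, except that TMM and median-of-ratios factors shift all basal-like genes alike, by 0.30 to 0.35. Of 620 alternative values of the 72 named gene folds, 3 reversed, 213 moved and 404 did not, and of 702 for the list medians 16 reversed and 102 moved. Of these 16, 6 under TMM and 5 under median-of-ratios scaling follow from that shared shift and say nothing about a list against other genes, and the counts of list members under both scalings move with it. Directions held under every alternative run for Lpar6, Cab39l and Krt15 levels, for the shares with Krt5 of the Lpar6 knockout and for the correlation of the folds. The number of lists outside the middle 95% stayed between 8 and 13 against 9, but different lists are among them, since 6 of 9 (Lpar6) and 4 of 9 (Cab39l) kept their side without the length trend. Each 9 counts the basal keratin list, which shares markers with the class and is no result within it.

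Class shares moved in 35 of 54 alternative values and reversed in 11. With at least 200 genes per cell instead of 500, the differences from wild type in points (Lpar6 and then Cab39l knockout) were -30.29 and -9.92 for basal-like and 12.01 and 20.8 for intermediate-like cells, and 42.14 for umbrella-like cells of the Lpar6 knockout, where the values used were -36.21, -17.66, 0.31, 2.74 and 15.63. With at least 1000 genes they were -34.03 for basal-like cells of the Lpar6 knockout, 7.89 for intermediate-like cells of the Cab39l knockout and 23.75 and 13.07 for umbrella-like cells. At most 10% mitochondrial UMIs gave -8.47 and 0.0 for basal-like and intermediate-like cells of the Cab39l knockout, and 8.55 and -7.2 for umbrella-like cells, the latter reversed from 17.15. With called doublets kept they were -33.37 for basal-like and 5.76 and 16.91 for intermediate-like cells, and 32.19 for umbrella-like cells of the Lpar6 knockout. Resolution 0.5 gave -62.91 and -44.07, then 2.14 and 17.5, then 47.2 and 23.75. Resolution 2 reversed the basal-like (0.55 and 18.86) and umbrella-like differences (-5.55 and -4.32) and gave -1.55 and 7.11 for intermediate-like cells. Centring the components per library reversed the same differences, to 7.52 and 23.89 and to -31.42 and -27.27, with 2.64 and 4.28 for intermediate-like cells. Clustering each library on its own gave 8.42 (reversed) and -1.71, then 1.61 and 5.72, then -6.88 (reversed) and 0.43. Clustering without fixed markers and genes 2-fold apart gave -27.62 and -12.82, then -1.34 and 1.29, and 23.94 for umbrella-like cells of the Lpar6 knockout.

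Without clusters, the share with Krt5 in the Lpar6 knockout, -13.61 points from wild type, was -4.83 without thinning and -9.11 with at least 200 genes. The Upk3a differences, both 0.81 points, were 0.0 and 0.0 at the 25th percentile of depth, 0.08 and 0.08 without thinning, 6.46 and 3.28 with at least 200 genes and 0.01 and 0.03 with at least 1000. Cycling cells, at -0.26 and -0.07 points, went to -1.37 and -2.29 at the 25th percentile and -0.81 and 0.34 without thinning, and in the Lpar6 knockout they reversed to 0.04 with at least 200 genes and 0.08 with doublets kept. The Krt15 share of the Cab39l knockout, 5.23 points above wild type, reversed to -1.22 at 10% mitochondrial UMIs, while that of the Lpar6 knockout stayed between -42.43 and -30.86. Depth limits these shares, since thinning to a lower depth leaves fewer markers to find in each cell.

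Among levels, given here as log2 of CPM ratios with no pseudocount, the Lpar6 log2 of -9.07 was -8.69 under TMM, -8.66 under median-of-ratios scaling, -8.80 at 10% mitochondrial UMIs and -9.19 with doublets kept, with its floor of 3 counts, and the Cab39l log2 of -1.82 was -1.43, -1.42 and -1.71 under the first 3. Krt15, at -2.26, was -1.88 and -1.86 under both scalings, -2.05 as the mean of cells, -2.33 with at least 1000 genes, -2.53 at 10% mitochondrial UMIs and -2.33 with doublets kept. With the pseudocount, Akr1b7 in intermediate-like cells reversed from 1.92 to -2.16 with at least 1000 genes, and Mfsd14a in umbrella-like cells from 1.07 to -0.15 at 10% mitochondrial UMIs and -0.19 over all urothelial-like cells.

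List members at least 1.5-fold higher in the Lpar6 knockout, 6 at the setting used, numbered 40 under TMM, 34 under median-of-ratios scaling, 10 with at least 1000 genes, 10 at 10% mitochondrial UMIs and 14 over all urothelial-like cells. Those lower, 90, numbered 30, 32, 34 at a pseudocount of 10 CPM, 136 over all urothelial-like cells and 26 in cluster 1 alone. In the Cab39l knockout the 2 higher became 36, 34, 5 as the mean of cells, 1 at 10 CPM, 4 with at least 1000 genes, 5 at 10% mitochondrial UMIs, 4 with doublets kept, 1 without the length trend and 10 over all urothelial-like cells. The 100 lower became 28, 29, 46 at 10 CPM and 25 in cluster 1 alone. List medians that reversed were nuclear oxidative phosphorylation without the length trend (-0.12 Lpar6, -0.09 Cab39l) and mitochondrially encoded genes, to 0.09 (Lpar6) and 0.13 (Cab39l) in cluster 1 alone and to 0.07 and 0.06 (Cab39l) under TMM and median-of-ratios scaling. Cholesterol synthesis reversed to 0.04, 0.02 and 0.03 (Lpar6) under TMM, median of ratios and in cluster 1 alone, and to 0.01 (Cab39l) under TMM. Progenitor genes reversed to 0.06 and 0.04 (Lpar6), NF-kB genes to 0.08 and 0.07 (Cab39l) and the genes near RB1 to 0.04 and 0.03 (Cab39l) under both scalings. The correlation of the folds, 0.868, was 0.888 at 10 CPM, 0.769 without the length trend, 0.915 over all urothelial-like cells and 0.677 in cluster 1 alone. A minimum of 200 UMIs removed no gene from it and says nothing.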

Other observations

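The tests of transcript length and of the position of genes around Lpar6, the count of cells holding mitosis genes and the comparison of cluster 1 alone were chosen only after the result was seen. Among urothelial-like cells, UMIs of the mitosis genes Ube2c, Cdk1 and Birc5 were concentrated in the umbrella-like cells of the Cab39l knockout. That class is named loosely, with 1 umbrella marker (Upk1b) and 1 intermediate marker (Psca) among its leading genes. After thinning, its Krt20 shares were 6.82% (wild type), 7.11% (Lpar6) and 6.42% (Cab39l). Over all urothelial-like cells they were 9.18, 6.81 and 5.38%, so these need not be umbrella cells. Of its 172 urothelial UMIs of Ube2c, 166 lay in umbrella-like cells (4.80 CPM), against 3 UMIs (0.134 CPM) in those of the Lpar6 knockout and 1 in wild type. Cdk1 had 66 UMIs there (1.91 CPM) against 0 and 0, and Birc5 88 UMIs (2.54 CPM) against 2 and 1. In umbrella-like cells the G2 and mitosis list stood above random lists in the Cab39l knockout over wild type, at 0.70 against 0.20 (percentile 98.9), as did S phase, at 0.40 against -0.07 (percentile 99.9). The Lpar6 over the Cab39l knockout gave -0.67 and -0.26, each at percentile 0.0. Very few cells carry the UMIs of the mitosis genes, while cells holding S phase genes were not counted. Ube2c UMIs were found in 9 of the 5032 urothelial-like cells of the Cab39l knockout, with 113 of them in 1 cell, and 5 cells held 396 of the 503 UMIs of Ube2c, Cdk1, Birc5, Mki67 and Ccnb1. Cells with 3 or more of these 5 genes numbered 1 in wild type, 0 in the Lpar6 knockout and 6 in the Cab39l knockout, and wild type had only 44 umbrella-like cells.

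In basal-like cells the knockouts differed from each other in 7 of the 32 lists, all on the same side after the length trend was taken off. Immediate early genes (0.26, percentile 100), MHC class I presentation (0.22, percentile 99.9), NRF2 targets (0.22, percentile 99.8), the mesenchymal list (0.22, percentile 98.2) and heat shock genes (0.15, percentile 99.1) were higher in the Lpar6 than in the Cab39l knockout, and uroplakins (-0.22, percentile 0.2) and junctions (-0.13, percentile 0.1) lower. In cluster 1 alone these lists gave 0.25, 0.23, 0.27, 0.20, 0.10, -0.18 and -0.11, with heat shock genes at percentile 95.1 and so inside the middle 95%. Among urothelial clusters, one led by Egr1, Jun, Fos and Zfp36 held 3.39% of kept wild-type, 10.2% of Lpar6 knockout and 6.34% of Cab39l knockout cells. Over all urothelial-like cells, however, Egr1 was 93.2, 26.7 and 22.5 CPM, Atf3 29.1, 3.51 and 9.10 CPM and Nr4a1 13.97, 1.29 and 2.92 CPM. A smaller cluster led by Atf3 and Nr4a1 held 80 wild-type cells against 3 and 4. Cirbp, the cold-inducible RNA-binding protein, was higher in both knockout libraries (187 and 175 CPM against 89.6 CPM). The mouse counterparts of genes near human RB1 lay among random lists in basal-like cells, at -0.20 (percentile 76.3) for Lpar6 and -0.29 (percentile 54.1) for Cab39l, which TMM and median-of-ratios scaling turned to 0.04 and 0.03 in the latter. Rb1, whose intron holds Lpar6, was 12.3, 7.71 and 5.52 CPM. Nnt, which differs between laboratory strains, was 2.08, 0.949 and 1.09 CPM.

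The first pattern weighed is a set of 132 transcripts, of 5492 eligible, at least 2-fold lower in both knockout libraries than in wild type, against 0 higher, on a scale where the median gene lies at -0.34 and -0.31 (in basal-like cells TMM scaling takes 44 lower and 0 higher to 7 and 7). The set includes Gm42418 (12190.1 CPM against 2060 and 1900 CPM, and in immune-like cells 17991 against 6208 and 3732 CPM, where Malat1, outside the set, was 21669 against 22407 and 16799 CPM but 21906 against 11186 and 9031 CPM in urothelial-like cells), and its median log2 relative to all genes was -0.75 (Lpar6) and -0.85 (Cab39l). Lower depth per cell of wild type is argued against as the cause. Cells of 20000 to 30000 UMIs (826, 2041 and 1044 cells) gave -0.80 and -0.85. The set was picked over all urothelial-like cells, which include these, so part of the value kept may be built in. Matching cells on UMIs says nothing on the quality of a library. Handling or RNA quality of the whole wild-type library cannot be told apart from a difference of urothelial cells. In immune-like cells the medians of the set were -0.29 (-0.45 to -0.20) and -0.20 (-0.29 to -0.13). Neither range reached the fall that handling was predicted to give. Both ranges span the bound set beforehand for counting against handling, and by the medians alone the Cab39l knockout lay past it. The use of these ranges was decided after the values. Uroplakins in the immune-like cells stood at 14.4, 25.7 and 23.5% of their urothelial level. A trend with transcript length likewise may account for part of the set (median 7.24 kb against 3.31 kb), which kept -0.38 and -0.40, or 50.7 and 47.9%, without it, and loss of either gene stays open and untested.

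The second pattern is a group of 20 genes, of 4322, that lie at least 1.5-fold apart, relative to the median gene, in the Lpar6 knockout from both other libraries, 12 higher and 8 lower. Chromosome 14 DNA around Lpar6 carried over from another mouse strain is a candidate explanation that stays open. Of the 20 genes, 2 (Adam28 and Dmtn) lie within 10 Mb of Lpar6 and 6 on its chromosome (among them Anxa8, 39.2 Mb away, Fam25c and Rnase4), but these positions had been seen before the test was chosen, so their number does not count for the explanation. A gain or loss of the whole segment within 10 Mb of Lpar6 is argued against by a median log2 of 0 over its 29 eligible genes. This is the Lpar6 over the Cab39l knockout, relative to all genes. A change of a smaller segment would not show in this median. Of the 8 genes set apart in the same way in the Cab39l knockout (among them Cd59a, Spink1, Gstp1, Defb1, Usp50, Grcc10 and Amd2), 0 lay within 10 Mb of Cab39l. Random sets of 8 genes matched on expression also had a median of 0 there, so this count cannot decide on carried-over DNA around Cab39l. An effect of the lost receptor on the genes of the first group was not tested.

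The third pattern is Krt15, which was lower in the Lpar6 knockout than in both other libraries, with a log2 of -2.25 over wild type and -2.30 over the Cab39l knockout. Fewer cells at the basal end alone were weighed by matching knockout cells on the 30 genes that go with Krt15 most. In matched cells the log2 was still -1.64 (302 against 941 CPM), past the bound set beforehand for counting against this cause. The match cannot decide it, because these genes had a median of -0.09 but went both ways. Krt5 stood at -0.78, Aldh3a1 at -0.70 and Nqo1 at 0.57, so matched cells may still differ in basal state. A lower Krt15 level within cells of like state is a hypothesis these values leave open. Whether it follows from loss of the receptor or from a strain variant in or near Krt15, which lies on chromosome 11, was not tested.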
